A study of Homo sapiens with 9 samples.

How the data were processed

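RNA sequencing was done on hTERT-MSC, a line of human mesenchymal stem cells from adipose tissue that was immortalised with telomerase. Per the labels' protocols, serum-starved cells were placed on inserts with pores of 3 µm, left for 2 h, and then given 50 ng/mL PDGF-BB, a growth factor that draws mesenchymal cells, in the well below for 1 h. Processes that had grown through the pores (pseudopodia) were scraped from the lower side, and the cell bodies were then scraped from the upper side. Whole-cell libraries carry the same treatment label, and their collection is not described separately. RNA was taken up in TRIzol with glycogen as carrier, and libraries were made with a kit for low input. Each of the 3 groups has 3 libraries. The labels do not say that these came from separate cultures, so p-values measure the spread between these samples, which may be technical.

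The read counts per gene were deposited by the authors as whole numbers, and the labels name featureCounts for that table. Per the submitters' processing notes the genome build was GRCh38 and DESeq2 was used. The aligner, the annotation release, the strand setting and the tool versions are not given in the sources used here. TPM values per library were also deposited by the authors. Counts and TPM differed by 1 constant per library and 1 length per gene, so both come from the same counting. The count table held 62709 genes with values and 1 blank line, which was left out. Of these genes, 37196 had a count in at least 1 library. Symbols came from the deposited TPM data for 28809 identifiers, and otherwise from a reference gene list that held 62638 of the identifiers. Positions came from GENCODE release 29 on GRCh38 for 58273. Genes with paralogs, pseudogene copies, overlapping neighbours or antisense partners are uncertain, since reads from such pairs may have been assigned to either.

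Library totals ran from 55469030 to 83894938 counts. A group of 3 libraries was compared with another in edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test with robust fitting, TMM factors and edgeR's expression filter by group, which left 19426 genes. All 9 libraries entered 1 fit with 1 spread per gene over all groups, and Benjamini-Hochberg adjusted p-values under 0.05 were called. The groups differed in spread (biological coefficient of variation 32.8% for pseudopodia, 17.6% for cell body and 5.08% for whole cell). P-values may thus be too small where pseudopodia are compared, and too large for cell body against whole cell. CPM values are normalised read counts scaled by library total and TMM factors, given as mean ± SD over 3 libraries. Standard errors of log2 fold changes were taken from the test statistic. On counts simulated from the real means, the test recovered 5.97% of genes changed 1.5-fold, 26.9% of those changed 2-fold and 80.3% of those changed 4-fold between pseudopodia and cell body, with 5 unchanged genes called among 18930 genes. For pseudopodia against whole cell the shares were 5.97%, 34.3% and 78.8%, with 15 unchanged genes called among 18911. For cell body against whole cell they were 2.99%, 29.9% and 83.3%, with 8 among 18913. These simulations gave all groups the same spread per gene, with an upper limit, and changed at most 67 genes per fold. They thus cannot show false calls under the unequal spread of the real groups. Nor do the recovered shares carry over to comparisons in which far more genes differ.

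Before the data were examined, 31 gene lists were fixed, among them markers of other cell types. Of their 882 entries, 881 matched the table. Each list was tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and limma's fry were alternatives. On simulated counts both of 2 shifted lists were called and 0 of the others. Those counts were drawn for each gene independently, so they cannot show false list calls that come from correlated genes. The named genes were also fixed by a rule: with a mean of at least 10 CPM, groups that do not overlap, an approved symbol and no sex-chromosome marker, the 10 highest and 10 lowest log2 fold changes per comparison, then up to 4 called members per list with a mean of at least 1 CPM, or up to 2 of the most abundant where none passed, and 12 fixed anchor genes. PKP4, DDR2, KANK2, DYNLL2 and CYB5R3, the remaining members of the protrusion list, were added after their values had been seen. Library measures were also computed after thinning and as shares of TPM, and were compared with a two-sided exact permutation test, whose smallest possible p with 3 against 3 is 0.1.

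Alternatives fixed in advance were DESeq2 size factors, upper-quartile factors, no mitochondrial and ribosomal protein genes, no low-count filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with sample weights, limma on log2(TPM + 1) and log2(TPM + 0.1), only the 6 libraries compared, a 2-fold minimum, the replicate number as a block, and each library left out in turn. A correction of each library for its trend with GC content and transcript length was added after seeing the data. GC content was known for 96.1% of the tested genes, and the correction took 3952 calls from a simulated GC trend to 0. Features of 3' UTRs and proteins were computed with Python 3.11.15 from GENCODE transcripts. Levels of XIST and of Y-linked genes were not reported.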

Results

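The data were gene counts of 9 RNA libraries from hTERT-MSC after 1 h of PDGF-BB, with 3 libraries each of pseudopodia, cell bodies and whole cells. Total counts were 74146421, 77166197 and 59148161 for pseudopodia. They were 55469030, 63261474 and 71330868 for cell body, and 83894938, 62834060 and 57233895 for whole cell. The first principal component held 62.7% of the variance and the next 18.7%. The spread between replicates, as a biological coefficient of variation, was 32.8% for pseudopodia, 17.6% for cell body and 5.08% for whole cell. Between any pair of replicates, chi-square per gene was 5.07 or more, so none differed by the counting noise of reads alone. Sampling of molecules before sequencing is not covered by this measure. Across genes, pseudopodia replicates 2 and 3 departed from their group mean with GC content in opposite directions (Pearson r = -0.56 and 0.57), while for replicate 1 r was -0.13 and for the other groups' libraries it lay between -0.048 and 0.068. Deviations of 3 libraries from their mean cancel out for each gene, so the opposite signs are largely fixed once replicate 1 deviates little. They do not show which of replicates 2 and 3 departs from the others. Replicates 2 and 3 also stood apart on the component with 7.36% of the variance, with scores of 54.3 and -61.1. Fold changes followed GC content across genes with r of 0.19 for pseudopodia against cell body, 0.31 against whole cell and 0.27 for cell body against whole cell. Genes are not independent replicates.

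**Figure D1:**
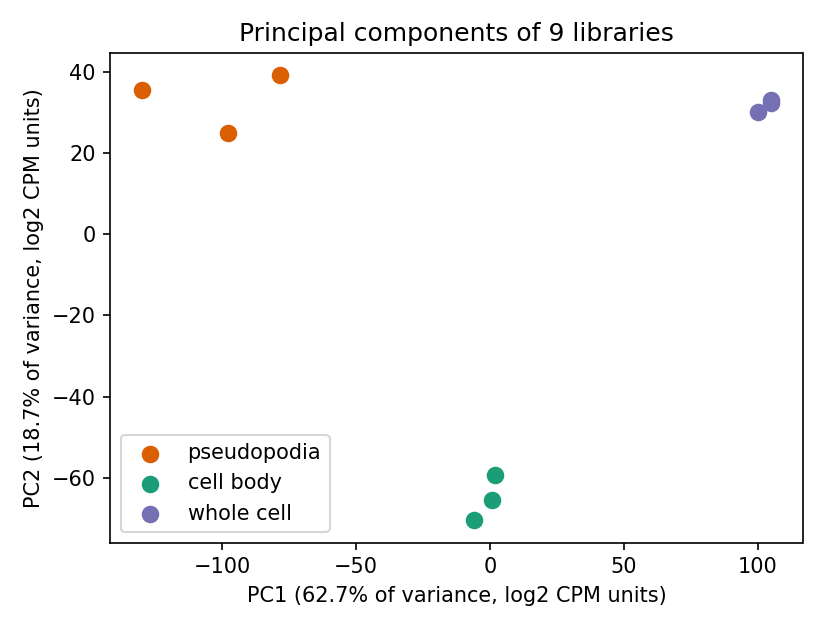
Scores of the 9 libraries on the leading principal components of log2 CPM, which hold 62.7% and 18.7% of the variance. Each point is 1 library, coloured by group, and on these the libraries of each group lie together.

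Mitochondrially encoded mRNAs took 6.02% ± 0.338 (SD, n = 3) of counts in pseudopodia, 2.84% ± 0.228 in cell body and 4.67% ± 0.277 in whole cell. Cytosolic ribosomal protein mRNAs took 7.0% ± 0.258, 4.82% ± 0.702 and 3.24% ± 0.202, and nuclear-retained lncRNAs 0.0310% ± 0.00401, 0.0573% ± 0.00157 and 0.115% ± 0.00142. After thinning every library to the smallest total, 24500 ± 673, 25830 ± 226 and 28460 ± 512 genes were detected. Each pair of groups differed in each of these measures with exact permutation p = 0.1, the smallest 3 against 3 can give. The share of the 50 most abundant genes was 22.5% ± 0.329 in pseudopodia and 23.3% ± 1.05 in cell body (exact permutation p = 0.4). In whole cell it was 26.2% ± 0.391.

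Pseudopodia were compared with cell bodies to ask which mRNAs differ between the protruding part of a migrating cell and its soma. RAB13, a small GTPase whose mRNA is a textbook example of localisation to protrusions, had 448.9 ± 46.5 CPM in pseudopodia and 20.33 ± 2.37 in cell body (SD, n = 3), a log2 fold change of 4.46 ± 0.151 (SE, adjusted p = 1.21e-08). KIF1C, a kinesin motor, rose from 151.8 ± 7.33 to 4292 ± 774 CPM (log2 fold change 4.82 ± 0.161), and TRAK2, an adaptor for mitochondrial transport, from 56.18 ± 8.78 to 1434 ± 67.0 CPM (4.67 ± 0.152). Lumican (LUM), a matrix proteoglycan, fell from 751.4 ± 102 to 97.33 ± 56.5 CPM (-2.95 ± 0.447), and the lncRNA MEG3 from 156.7 ± 15.3 to 16.10 ± 2.38 CPM (-3.28 ± 0.147). RAB13 (ENSG00000143545) lies on chromosome 1 at 153981617 to 153986358 of GRCh38, KIF1C (ENSG00000129250) on chromosome 17 at 4997948 to 5028401, and TRAK2 (ENSG00000115993) on chromosome 2 at 201377207 to 201451579. LUM (ENSG00000139329) lies on chromosome 12 at 91102629 to 91111831 and MEG3 (ENSG00000214548) on chromosome 14 at 100779410 to 100861031.

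Of 19426 genes, 3605 were higher and 3870 lower in pseudopodia than in cell body (edgeR's quasi-likelihood test, 7475 together), of which 1690 and 2396 differed at least 2-fold. The other genes with the highest log2 fold changes were CHD9NB, ZSWIM9, RASSF3, NBPF10, VASH1, GDF11, SH3PXD2A and C1orf115, between 4.48 for C1orf115 and 4.87 for CHD9NB. SH3PXD2A encodes the podosome scaffold TKS5 and GDF11 a ligand of the TGF-beta family, while NBPF10 belongs to a family of near-identical genes and is uncertain. The lowest were MIR222HG, CARMN, POSTN, MATN2, LRRC17, TNFAIP6, ENPP2 and ABI3BP, between -3.25 for MIR222HG and -2.90 for ABI3BP. Without pseudopodia replicate 2 the values were -3.98 for MIR222HG and -4.16 for POSTN (-3.14 with it). POSTN (periostin), MATN2 and ABI3BP encode matrix proteins and ENPP2 the secreted enzyme autotaxin. Of the anchors, ACTB (log2 fold change -0.26, adjusted p = 0.138), VIM (-0.49, 0.152) and NEAT1 (0.05, 0.755) did not pass the test in edgeR. GAPDH rose (0.52, adjusted p = 0.0157) and COL1A1 fell (-0.49, 0.0217), and without cell body replicate 2 both lost the call (0.0512 and 0.0886). GAPDH also lost it on log2(TPM + 1) (0.21, adjusted p = 0.155) and with only the 6 libraries compared (0.46, 0.0514), and VIM passed on log2(TPM + 1) (-0.85, 0.0349). ACTB passed with 6 of the alternative fits and without pseudopodia replicate 3 (-0.39, adjusted p = 0.0115), always lower in pseudopodia.

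Of the protrusion list, mRNAs known from earlier work to depend on APC or to localise with RAB13, 9 of 10 rose and 0 fell (9 and 0 adjusted over the list alone). NET1, a guanine nucleotide exchange factor, rose by 3.84 ± 0.299 on the log2 scale, RASSF3 by 4.74, PKP4 by 3.87, DDR2 by 3.67, DYNLL2 by 2.47 and KANK2 by 2.47. CYB5R3 stood at 582.1 CPM in pseudopodia and 557 in cell body (adjusted p = 0.755). The camera test gave adjusted p = 1.83e-10 for this list, and adjusted p = 0.0467 with an estimated correlation.

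Ribosomal protein mRNAs rose in 63 of 80 cases and fell in 2 (65 and 2 adjusted over the list alone, camera adjusted p = 3.31e-11, adjusted p = 0.355 with an estimated correlation). RPS2 rose from 1803 ± 65.8 to 3929 ± 705 CPM and RPL12 from 921.4 ± 56.2 to 1907 ± 163 CPM. Ribosomal protein genes have many processed pseudogenes, so single members are uncertain. Their share of counts was also higher in pseudopodia, as given above. All 13 mitochondrially encoded mRNAs rose (13 adjusted over the list alone, camera adjusted p = 6.29e-07, adjusted p = 0.204 with an estimated correlation), and their share of counts was higher too, as given above. MT-CO1, a subunit of cytochrome c oxidase, rose from 11870 ± 729 to 31300 ± 2330 CPM. Chromatin regulators rose in 28 of 33 cases and fell in 0 (28 and 0 adjusted over the list alone, camera adjusted p = 4.16e-10, adjusted p = 0.119 with an estimated correlation), among them the remodeller CHD2 with a log2 fold change of 2.62 and the DNA methyltransferase DNMT3A with 1.92.

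Extracellular matrix genes fell in 37 of 40 cases and rose in 0 (37 and 0 adjusted over the list alone, camera adjusted p = 1.51e-14, adjusted p = 0.0913 with an estimated correlation). LOX, which crosslinks collagen, fell from 1201 ± 210 to 201.8 ± 123 CPM and the proteoglycan VCAN from 118.7 ± 65.0 to 17.12 ± 6.59 CPM. Genes of the endoplasmic reticulum and secretory pathway fell in 24 of 33 cases and rose in 0 (24 and 0 adjusted over the list alone, camera adjusted p = 4.56e-09, adjusted p = 0.0913 with an estimated correlation). HSPA5, the chaperone BiP, fell from 569.7 ± 12.9 to 105.2 ± 16.9 CPM and the disulfide isomerase PDIA3 from 712.2 ± 22.3 to 177.5 ± 17.3 CPM. Mesenchymal stem cell and fibroblast markers fell in 11 of 14 cases and rose in 1 (11 and 1 adjusted over the list alone, camera adjusted p = 0.000519, adjusted p = 0.0913 with an estimated correlation), among them the hyaluronan receptor CD44 (-1.73) and PDGFRB (-0.81), a receptor of PDGF-BB, while the intermediate filament NES rose (2.15). Cholesterol synthesis genes fell in 12 of 20 cases and rose in 0 (14 and 1 adjusted over the list alone, camera adjusted p = 0.00264, adjusted p = 0.119 with an estimated correlation), among them MSMO1 (-1.63).

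Immediate early genes fell in 23 of 44 cases and rose in 3 (24 and 3 adjusted over the list alone, camera adjusted p = 0.00264, adjusted p = 0.43 with an estimated correlation). FOS fell from 78.26 ± 10.4 to 44.60 ± 7.66 CPM and CCN2 from 372.5 ± 30.3 to 105.3 ± 18.0 CPM, while the small MAF factor MAFF rose from 107.3 ± 11.3 to 914.4 ± 213 CPM. EGR1 (-0.53, adjusted p = 0.0399) lost its call without pseudopodia replicate 2 (adjusted p = 0.0966), without pseudopodia replicate 3 (0.0504), and without cell body replicate 1 (0.116) or replicate 2 (0.161). It lost it too with limma-voom (0.111) and with only the 6 libraries compared (0.0602). Nuclear-retained lncRNAs fell in 8 of 11 cases and rose in 0 (8 and 0 adjusted over the list alone, camera adjusted p = 0.00434, adjusted p = 0.15 with an estimated correlation). Under the stricter filter of 5 CPM adjusted p was 0.086. Their share of counts was lower in pseudopodia too. TUG1 fell from 114.8 ± 22 to 64.82 ± 6.21 CPM. MALAT1 had 0.233 ± 0.116 CPM in pseudopodia and 0.851 ± 0.343 in cell body (log2 fold change -1.83, adjusted p = 0.00263). MALAT1 is among the most abundant nuclear RNAs in many cells, but here it had 3.681 ± 0.33 CPM even in whole cell. The strand setting and annotation of the counts are not known, so its fold changes are uncertain, and the share of nuclear lncRNAs is counted almost without it. Chondrogenic genes fell in 6 of 9 cases and rose in 1 (6 and 1 adjusted over the list alone, camera adjusted p = 0.0071, adjusted p = 0.119 with an estimated correlation), among them ACAN and COMP. Cell cycle genes fell in 11 of 30 cases and rose in 2 (12 and 3 adjusted over the list alone, camera adjusted p = 0.027, adjusted p = 0.119 with an estimated correlation), among them BUB1 and CDK1. Without cell body replicate 2 adjusted p was 0.058.

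**Figure D2:**
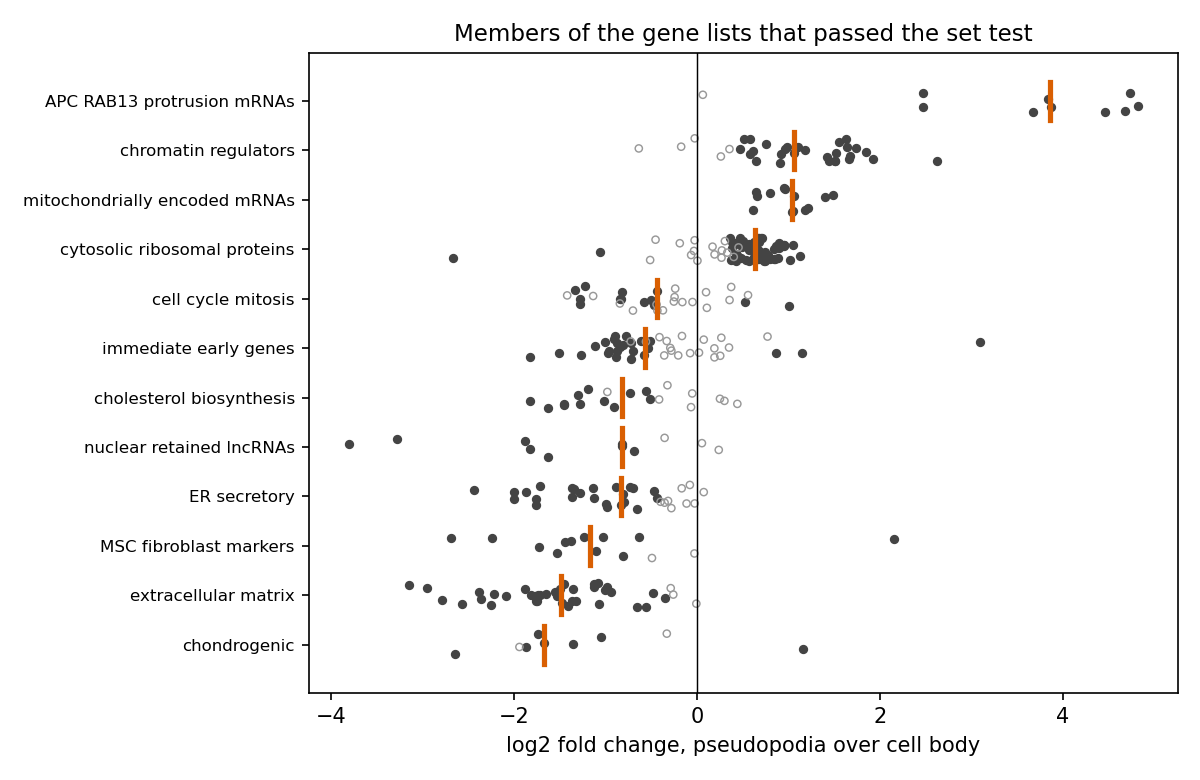
Log2 fold change of pseudopodia over cell body for each tested member of the 12 lists that passed the camera test. Filled points passed the test per gene, open points did not, and the bar is the list's median, 3.86 for the protrusion list and -1.49 for extracellular matrix.

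The other 19 lists did not pass the camera test between pseudopodia and cell body. The lowest adjusted p was 0.0537, for interferon response. Their members called higher and lower were 10 and 4 of 35 translation factors, 5 and 8 of 72 nuclear genes of oxidative phosphorylation, 10 and 4 of 28 genes of PDGF receptor signalling, 16 and 6 of 58 actin genes, 5 and 15 of 29 focal adhesion genes, and 11 and 5 of 30 genes of microtubules and transport. They were 5 and 4 of 34 genes of endocytosis, 3 and 6 of 19 of glycolysis, 5 and 7 of 20 YAP and TEAD targets, 10 and 7 of 32 mechanosensitive transcription factors, 7 and 16 of 45 spliceosome genes, 1 and 4 of 31 proteasome genes, 2 and 10 of 20 interferon response genes and 3 and 8 of 22 heat shock and stress genes. Lineage and cell type markers gave 0 and 6 of 8 osteogenic, 2 and 1 of 7 adipocyte, 2 and 4 of 10 endothelial, 0 and 1 of 5 haematopoietic and 0 and 0 of 8 epithelial genes. Adjusted over the list alone, the counts were 7 and 18 for focal adhesion, 3 and 4 for oxidative phosphorylation, 11 and 5 for PDGF receptor signalling and 12 and 5 for microtubules. They were 10 and 8 for mechanosensitive transcription factors, 8 and 16 for the spliceosome, 1 and 2 for the proteasome, 2 and 5 for endothelial markers, and equal for the rest. Focal adhesion (adjusted p = 0.0695) passed without pseudopodia replicate 3 (0.0224) or cell body replicate 1 (0.0387) and after the GC and length correction (0.00391). The proteasome list (0.143) passed without pseudopodia replicate 3 (0.0275). Interferon response passed without pseudopodia replicate 2 (0.0467), cell body replicate 2 (0.0491) or cell body replicate 3 (0.0488), and after the GC and length correction (0.0238), as did osteogenic genes (0.0966, corrected 0.0372). For mechanosensitive transcription factors the median was -0.05 and the mean 0.24, and the test pointed up. Single members rose far, the dynein chain DYNC1LI2 by 3.15, the kinesin KIF3B by 3.10, the microtubule protein MAP4 by 2.92, the phosphatase PTPN11 by 3.00, the adhesion protein TNS1 by 2.74 and the transcription factor ERG by 4.35 on the log2 scale. Others fell, among them the integrins ITGA4 (-2.11, and -2.74 without pseudopodia replicate 2) and ITGA1 (-2.04) and the cadherin CDH5 (-2.12).

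With the preset correlation 12 lists passed and with an estimated one 1. On deposited TPM without composition scaling, the log2(TPM + 1) fit called 2310 higher and 5907 lower, with a median shift of -0.28 in log2 fold change. The GC and length correction called 4665 higher and 4011 lower, which turns the majority.

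Pseudopodia were compared with whole cells to set the fraction against unfractionated RNA. NFATC2, a calcium-regulated transcription factor, had 414.5 ± 44.8 CPM in pseudopodia and 0.459 ± 0.0859 in whole cell (SD, n = 3), a log2 fold change of 9.81 ± 0.311 (SE, adjusted p = 1.2e-08). RAB13 rose from 19.43 ± 1.32 to 448.9 ± 46.5 CPM (4.53 ± 0.152), and HBEGF, a ligand of the EGF receptor, from 1.287 ± 0.187 to 36.06 ± 3.85 CPM (4.81 ± 0.166). FOS, an immediate early transcription factor, fell from 1772 ± 33.6 to 44.60 ± 7.66 CPM (-5.31 ± 0.180), and POSTN from 2133 ± 12.7 to 68.00 ± 59.6 CPM (-4.97 ± 0.589, and -5.98 without pseudopodia replicate 2). NFATC2 (ENSG00000101096) lies on chromosome 20 at 51386957 to 51562831, HBEGF (ENSG00000113070) on chromosome 5 at 140332843 to 140346631, and FOS (ENSG00000170345) on chromosome 14 at 75278774 to 75282230.

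In this comparison 5412 genes were higher and 6430 lower (edgeR, 11842 together), of which 2824 and 4793 differed at least 2-fold. The other genes with the highest log2 fold changes were IL21R, DCLK3, HEYL, MAFK, PGF, S1PR5, ETS1 and LINC00511, from 4.75 for LINC00511 to 8.18 for IL21R. HEYL is a Notch target, PGF an angiogenic growth factor and ETS1 a transcription factor. The other lowest were IGSF10, CCNL1, TTC14, RSRP1, ABI3BP, ANGPT1, ADM and VCAN, from -5.51 for IGSF10 to -4.21 for VCAN. Without pseudopodia replicate 2 TTC14 was at -6.22 (-5.28 with it) and ANGPT1 at -5.42 (-4.40 with it). EGR1 fell by 1.88, NEAT1 fell by 1.75 and GAPDH rose by 0.89 on the log2 scale, and MALAT1, uncertain as above, fell by 3.94. ACTB did not pass (0.05, adjusted p = 0.769) but on log2(TPM + 1) was reversed and passed (-0.42, adjusted p = 0.0025 in limma). VIM did not pass either (-0.27, adjusted p = 0.379) but did on log2(TPM + 1) (-0.81, 0.028). PDGFRB (-0.25, adjusted p = 0.194) passed without pseudopodia replicate 3 (-0.41, 0.0194), with 5 CPM in 3 libraries (0.0391), with limma-voom, on TPM and after the GC and length correction. MT-CO1 rose by 0.81 and NET1 by 3.87 on the log2 scale. COL1A1 fell (-0.49, adjusted p = 0.0136), with adjusted p = 0.05 without whole cell replicate 1.

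All 10 protrusion mRNAs rose (10 adjusted over the list alone, camera adjusted p = 1.59e-07, adjusted p = 0.104 with an estimated correlation). Ribosomal protein mRNAs rose in 72 of 80 cases and fell in 1 (72 and 1 adjusted over the list alone, camera adjusted p = 4.69e-19, adjusted p = 0.229 with an estimated correlation), among them RPL12 and RPS2. Nuclear genes of oxidative phosphorylation rose in 45 of 72 cases and fell in 2 (46 and 2 adjusted over the list alone, camera adjusted p = 6.7e-06, adjusted p = 0.385 with an estimated correlation). Translation factors rose in 20 of 35 cases and fell in 3 (20 and 3 adjusted over the list alone, camera adjusted p = 0.00271, adjusted p = 0.12 with an estimated correlation), among them EIF4G1 and EIF4B. Chromatin regulators rose in 22 of 33 cases and fell in 3 (22 and 3 adjusted over the list alone, camera adjusted p = 4.53e-05, adjusted p = 0.245 with an estimated correlation), among them TET3 and KDM6B. Actin genes rose in 32 of 58 cases and fell in 7 (32 and 7 adjusted over the list alone, camera adjusted p = 0.000755, adjusted p = 0.229 with an estimated correlation), among them ARPC5L of the Arp2/3 complex. Mechanosensitive transcription factors rose in 18 of 32 cases and fell in 8 (18 and 9 adjusted over the list alone, camera adjusted p = 0.0111, adjusted p = 0.359 with an estimated correlation), among them TEAD4 and SNAI1. Proteasome genes rose in 18 of 31 cases and fell in 2 (18 and 2 adjusted over the list alone, camera adjusted p = 0.0201, adjusted p = 0.302 with an estimated correlation). Genes of endocytosis, with a median of 0.30 that on log2(TPM + 1) was -0.17, rose in 17 of 34 cases and fell in 6 (18 and 6 adjusted over the list alone, camera adjusted p = 0.0201, adjusted p = 0.229 with an estimated correlation).

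Genes of microtubules and transport, with a median of 0.34 that on log2(TPM + 1) was -0.12, rose in 16 of 30 cases and fell in 7 (16 and 8 adjusted over the list alone, camera adjusted p = 0.0424, adjusted p = 0.229 with an estimated correlation). Without pseudopodia replicate 2 adjusted p was 0.0561. Mitochondrially encoded mRNAs, with a median of 0.29 that on log2(TPM + 1) was -0.17, rose in 6 of 13 cases and fell in 0 (6 and 0 adjusted over the list alone, camera adjusted p = 0.0467, adjusted p = 0.542 with an estimated correlation). That call was lost without pseudopodia replicate 2 (adjusted p = 0.0585), and without whole cell replicate 1 (0.0778) or replicate 2 (0.0502). Extracellular matrix genes fell in 32 of 40 cases and rose in 2 (32 and 2 adjusted over the list alone, camera adjusted p = 5.61e-06, adjusted p = 0.229 with an estimated correlation), among them LOX and the laminin LAMB1. Nuclear-retained lncRNAs, whose share of counts was lower in pseudopodia, fell in 9 of 11 cases and rose in 0 (9 and 0 adjusted over the list alone, camera adjusted p = 0.000885, adjusted p = 0.198 with an estimated correlation), among them MEG3, from 287.0 ± 10.3 to 16.10 ± 2.38 CPM. Cell cycle genes fell in 17 of 30 cases and rose in 4 (17 and 4 adjusted over the list alone, camera adjusted p = 0.0242, adjusted p = 0.198 with an estimated correlation), among them TOP2A and MKI67. Chondrogenic genes fell in 7 of 9 cases and rose in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.0201, adjusted p = 0.198 with an estimated correlation), among them HAPLN1.

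With the stricter filter of 5 CPM the endocytosis (adjusted p = 0.112), chondrogenic (0.143), microtubule (0.167) and mitochondrial (0.24) lists did not pass. The other 16 lists did not pass, with adjusted p from 0.0516 for mesenchymal stem cell and fibroblast markers to 0.923 for endothelial and haematopoietic markers. Those markers of mesenchymal cells passed without pseudopodia replicate 3 (0.0252), as did the secretory pathway (0.0696, without it 0.0474), and glycolysis (0.0773) passed without pseudopodia replicate 2 (0.0251). The filter of 5 CPM gave 0.0311 for mesenchymal markers and 0.00848 for the secretory pathway, whose median of -0.35 was 0.06 after the GC and length correction (adjusted p = 0.435), and that correction gave 0.00348 for mesenchymal markers and 0.0455 for the spliceosome. Median, mean and test differed in sign for immediate early genes (-0.28, 0.15, up), YAP and TEAD targets (0.08, -0.35, down) and endothelial markers (-0.18, 0.15, down), none of which passed. The log2(TPM + 1) fit called 3227 higher and 9687 lower, with a median shift of -0.44. The GC and length correction called 7115 higher and 5402 lower. The labels do not say how whole cells were collected, so handling and fraction differ together here.

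Cell bodies were compared with whole cells to show how the soma fraction differs from unfractionated RNA. NFATC2 had 125.7 ± 38.3 CPM in cell body and 0.459 ± 0.0859 in whole cell (log2 fold change 8.09 ± 0.293, adjusted p = 1.04e-07 in edgeR), while XIRP1, an actin-binding protein of muscle, had 36.28 ± 8.63 and 0.0784 ± 0.0165 CPM (8.85 ± 0.338). XIRP1 (ENSG00000168334) lies on chromosome 3 at 39183210 to 39192596. HBEGF rose from 1.287 ± 0.187 to 31.60 ± 0.156 CPM (4.62 ± 0.164). FOS fell from 1772 ± 33.6 to 78.26 ± 10.4 CPM (adjusted p = 1.04e-07), and ADM, the peptide hormone adrenomedullin, from 427.5 ± 16.3 to 46.33 ± 12.3 CPM (-3.21 ± 0.199). RAB13 (20.33 ± 2.37 and 19.43 ± 1.32 CPM, adjusted p = 0.722) and NET1 (25.49 ± 2.51 and 25.08 ± 0.368 CPM, 0.955) did not pass the test.

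**Figure D3:**
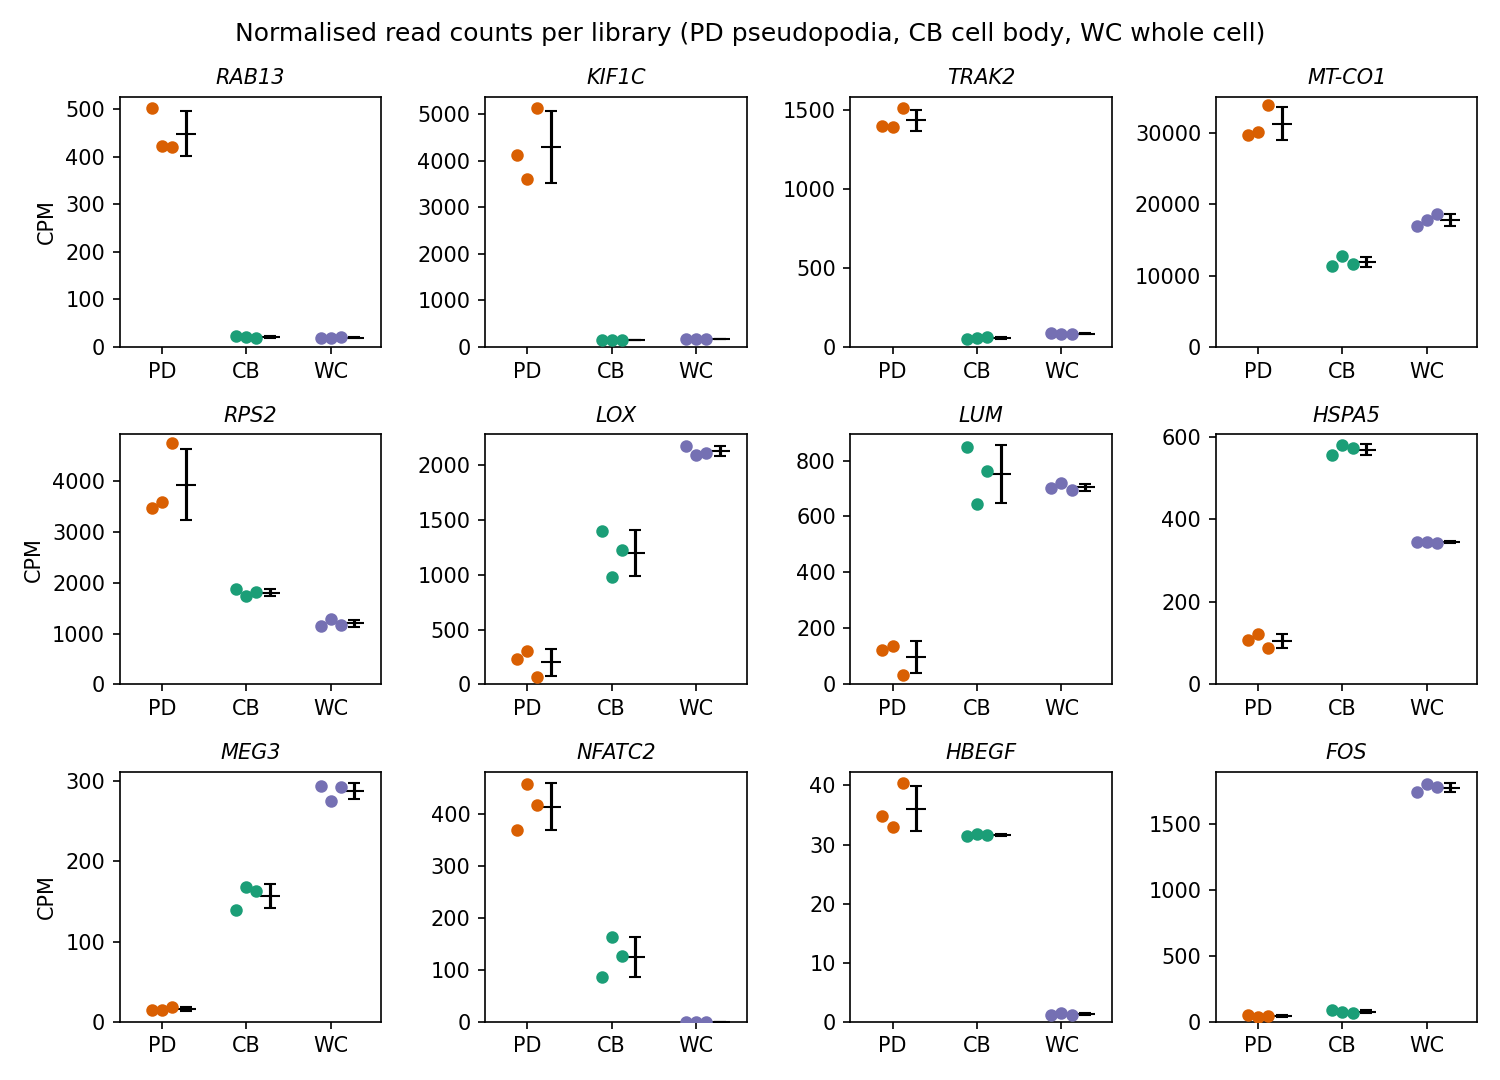
Normalised read counts (CPM, linear axis from 0) of 12 named genes in each library of pseudopodia (PD), cell body (CB) and whole cell (WC). Coloured points are libraries, and the black mark and bar are mean and SD over 3 libraries. RAB13 stands at 448.9 CPM in pseudopodia and 20.33 in cell body, and FOS at 1772 CPM in whole cell.

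Between cell body and whole cell 3521 genes were higher and 3980 lower (edgeR, 7501 together), of which 1059 and 2821 differed at least 2-fold. The other genes with the highest log2 fold changes were HEYL, CLDN14, NR4A3, PGF, DLX3, HAS2 and S1PR5, from 4.62 for S1PR5 to 6.65 for HEYL. HAS2 makes hyaluronan and NR4A3 is an immediate early nuclear receptor. The other lowest were NFKBIZ, FGF7, APC, SIM1, CKAP2, PHF3, KTN1 and BAZ2B, from -3.51 for NFKBIZ to -3.22 for BAZ2B. KTN1 did not pass with no low-count filter (adjusted p = 0.0501). Without cell body replicate 2 APC was at -4.06 (-3.45 with it) and PHF3 at -4.03 (-3.38 with it). The anchors MT-CO1 (-0.58), NEAT1 (-1.81) and EGR1 (-1.35) fell and PDGFRB (0.56) rose, while ACTB (0.31, adjusted p = 0.0826), GAPDH (0.37, 0.069), VIM (0.22, 0.511) and COL1A1 (adjusted p = 0.997) did not pass. MALAT1, uncertain as above, fell by 2.12. ACTB and GAPDH passed with 5 of the alternatives each, for example with only the 6 libraries compared (0.00572 and 0.00186). PDGFRB (adjusted p = 0.0193) lost its call without cell body replicate 2 (0.0682) or replicate 3 (0.0532), and without whole cell replicate 1 (0.0545), replicate 2 (0.0587) or replicate 3 (0.0574), and on log2(TPM + 1) (0.0602).

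Ribosomal protein mRNAs, whose share of counts was higher in cell body, rose in 73 of 80 cases and fell in 0 (74 and 0 adjusted over the list alone, camera adjusted p = 2.39e-19, adjusted p = 0.255 with an estimated correlation). Nuclear genes of oxidative phosphorylation rose in 49 of 72 cases and fell in 1 (53 and 1 adjusted over the list alone, camera adjusted p = 3.05e-11, adjusted p = 0.26 with an estimated correlation). Genes of the secretory pathway rose in 22 of 33 cases and fell in 1 (25 and 1 adjusted over the list alone, camera adjusted p = 7.99e-07, adjusted p = 0.107 with an estimated correlation), among them SEC61B and SEC13. The chaperone HSP90B1 fell (-1.62, adjusted p = 0.0249) but lost its call without cell body replicate 1 (0.0515) or replicate 3 (0.0753). It did so too without whole cell replicate 1 (0.0636), replicate 2 (0.0636) or replicate 3 (0.0599), and with no low-count filter (0.115). Cholesterol genes rose in 13 of 20 cases and fell in 0 (14 and 0 adjusted over the list alone, camera adjusted p = 6.59e-05, adjusted p = 0.101 with an estimated correlation). INSIG1, a regulator of sterol synthesis, rose from 28.05 ± 0.833 to 133.7 ± 11.3 CPM. Heat shock and stress genes rose in 14 of 22 cases and fell in 0 (16 and 2 adjusted over the list alone, camera adjusted p = 0.000123, adjusted p = 0.126 with an estimated correlation), among them HMOX1, which degrades haem, from 23.83 ± 0.796 to 186.7 ± 6.74 CPM. Glycolysis genes rose in 11 of 19 cases and fell in 0 (12 and 1 adjusted over the list alone, camera adjusted p = 0.000171, adjusted p = 0.509 with an estimated correlation), among them HK2 and SLC2A1. Proteasome genes rose in 21 of 31 cases and fell in 0 (22 and 0 adjusted over the list alone, camera adjusted p = 1.34e-06, adjusted p = 0.107 with an estimated correlation), among them PSMC4.

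Spliceosome genes rose in 21 of 45 cases and fell in 2 (27 and 2 adjusted over the list alone, camera adjusted p = 0.000162, adjusted p = 0.0841 with an estimated correlation), and SRSF11 was among the lower. Actin genes rose in 25 of 58 cases and fell in 3 (28 and 4 adjusted over the list alone, camera adjusted p = 9.52e-05, adjusted p = 0.237 with an estimated correlation). Translation factors rose in 16 of 35 cases and fell in 1 (16 and 2 adjusted over the list alone, camera adjusted p = 0.00152, adjusted p = 0.101 with an estimated correlation), among them EIF5. Genes of endocytosis rose in 12 of 34 cases and fell in 1 (13 and 1 adjusted over the list alone, camera adjusted p = 0.00315, adjusted p = 0.126 with an estimated correlation), among them EHD1. Under the filter of 5 CPM adjusted p was 0.0582. Mechanosensitive transcription factors rose in 13 of 32 cases and fell in 3 (13 and 3 adjusted over the list alone, camera adjusted p = 0.00466, adjusted p = 0.432 with an estimated correlation), among them SNAI1 and SOX9, while ZEB1 fell (-3.04, and -3.99 without cell body replicate 2). Immediate early genes rose in 21 of 44 cases and fell in 13 (22 and 15 adjusted over the list alone, camera adjusted p = 0.0324, adjusted p = 0.562 with an estimated correlation). FOSL1 rose by 3.59 and NR4A3 by 5.38 on the log2 scale. That call was lost without cell body replicate 1 (adjusted p = 0.0767), under the filter of 5 CPM (0.429) and after the GC and length correction (0.28). Mitochondrially encoded mRNAs, whose share of counts was lower in cell body, fell in 10 of 13 cases and rose in 0 (10 and 0 adjusted over the list alone, camera adjusted p = 0.0013, adjusted p = 0.469 with an estimated correlation), among them MT-ND4 and MT-ND2. Nuclear-retained lncRNAs fell in 7 of 11 cases and rose in 2 (7 and 2 adjusted over the list alone, camera adjusted p = 0.0155, adjusted p = 0.255 with an estimated correlation). After the GC and length correction adjusted p was 0.103. Of the protrusion mRNAs 4 of 10 fell and 0 rose (4 and 0 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.4, adjusted p = 0.562 with an estimated correlation). The other 16 lists, this one included, had adjusted p from 0.0609 for extracellular matrix to 0.947 for interferon response. Extracellular matrix passed without cell body replicate 1 (0.00468) or whole cell replicate 3 (0.0485).

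Median, mean and test differed in sign for PDGF receptor signalling (0.12, -0.17, up), microtubules and transport (0.03, -0.11, up), YAP and TEAD targets (-0.17, -0.03, up), osteogenic genes (0.08, -0.07, up) and epithelial markers (0.27, -0.02, up), none of which passed. The log2(TPM + 1) fit called 2643 higher and 5898 lower, with a median shift of -0.17. The GC and length correction called 5637 higher and 3865 lower. How whole cells were collected is not given, so handling may differ with the group here too.

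Genes that differed in pseudopodia from both other groups in the same direction numbered 5843, with 2823 higher, RAB13, NET1, KIF1C and TRAK2 among them, and 3020 lower, POSTN, FOS and MEG3 among them. After the GC and length correction 3735 were higher and 2890 lower. Independent lists of these sizes would share 1004 higher and 1281 lower genes. The 3 pseudopodia libraries enter both comparisons and are too few to be split, so part of the excess over independent lists may come from sharing them. Groups simulated without any difference gave an overlap of 0 in 20 simulations. As no gene differs there, this cannot gauge the overlap that shared libraries add where many genes differ.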

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

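The GC and length correction was chosen after the results were seen and the other alternatives before. Of 239 named gene results, 212 kept direction and side of the threshold under every alternative run. Many of these genes were picked in the same data for large called changes, so this does not speak for all called genes. Over 4510 recomputed values, 67 lost and 28 gained a call. ACTB in pseudopodia against whole cell turned from 0.05 to -0.42 with each of the 3 TPM fits, which apply no composition scaling; further causes were not tested.

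Requiring a 2-fold change left 4086 genes for pseudopodia against cell body, 7617 against whole cell, 3880 for cell body against whole cell and 3074 for pseudopodia against both, by construction. With 5 CPM in 3 libraries, where fewer genes are tested, 7516 and 4667 genes were called in the comparisons of pseudopodia and of cell body with whole cell. With limma-voom cell body against whole cell gave 11967, and the cause was not tested. An estimated correlation called 1, 0 and 0 lists, and fry, which does not compare a list with other genes, 26, 26 and 23. DESeq2 called 7757, 11876 and 7713 genes, and 6021 for both. With a library left out the counts ran from 6034 to 8581, 10283 to 12667, 5049 to 6331 and 4925 to 6906, and the lists from 12 to 14, 14 to 17 and 15 to 16.

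As shares of TPM, which weight short abundant transcripts, mitochondrial mRNA differed by 9.14 percentage points between pseudopodia and cell body, 1.73 between pseudopodia and whole cell and -7.40 between cell body and whole cell. Nuclear lncRNA differed by -0.0118, -0.0210 and -0.00921, ribosomal protein mRNA by 4.24 between pseudopodia and whole cell, and the 50 most abundant genes by 8.67 and 2.95, both reversed, and -5.71.

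No pairing by replicate number was detected. Same-numbered deviations correlated from -0.081 to 0.09 over 9 pairs of a library and a comparison, and in 1 of the 9 the own number matched best. The labels do not say whether same-numbered fractions came from the same insert. So few libraries cannot exclude such pairing, which the main fit leaves out. With the number as a block 6920, 11494, 6798 and 5427 genes and 12, 13 and 15 lists were called. Among list calls it ended those of the mitochondrial and microtubule lists in pseudopodia against whole cell (adjusted p = 0.0525 and 0.0541), and among genes that of EGR1 in pseudopodia against cell body (0.063). At depths of 55469030 counts or more, with a biological coefficient of variation of 32.8% in pseudopodia, the spread between 3 libraries limits what can be called more than counting error does.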

Other observations

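Chosen after the result was seen were the 32 gene families, the GC tests, the test of whole cells as a sum of the fractions, the reverse-complement control for the motif and the planted motifs. The genes given as examples of families and the members with almost no counts were chosen after their values were seen. The hydrophobic-segment test was written after matrix and secretory lists had been seen lower.

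Among 32 families of related gene symbols, tested with camera, protocadherins, cell adhesion proteins of neighbouring gene clusters, fell in pseudopodia against cell body in 40 of 43 cases (adjusted p = 2.19e-19, adjusted p = 0.153 with an estimated correlation). PCDHGB5 fell from 68.1 to 11.5 CPM, though members share exons or close sequence and are uncertain. Cathepsins, lysosomal proteases, fell in 11 of 12 cases (adjusted p = 2.33e-06, adjusted p = 0.106 with an estimated correlation), with CTSK at 473 CPM in cell body and 122 in pseudopodia. Solute carriers fell in 132 of 271 cases and rose in 23 (adjusted p = 4.88e-06, adjusted p = 0.172 with an estimated correlation). Enzymes of lysine methylation rose in 20 of 25 cases (adjusted p = 7.56e-07, adjusted p = 0.153 with an estimated correlation), with KMT2B at 191 and 41.9 CPM. This family shares genes, KMT2A and KDM6B among them, with the list of chromatin regulators above, so it adds no independent result. Kinases upstream of MAP kinases (MAP2K, MAP3K and MAP4K genes) rose in 14 of 28 cases (adjusted p = 0.000407, adjusted p = 0.106 with an estimated correlation), with MAP4K4 at 5770 and 458 CPM.

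A hypothesis was that mRNAs of membrane and secreted proteins stay behind in the cell body. Among coding genes outside the fixed lists, 4706 encode a protein with a hydrophobic segment of 19 residues and 8389 do not. Their median log2 fold changes, pseudopodia over cell body, were -0.38 and 0.06, a difference of -0.44 (camera p = 3.95e-08, p = 0.0136 with an estimated correlation), in line with the hypothesis. Between cell body and whole cell the difference was 0.02 and did not pass camera. That lncRNAs stay behind in the cell body was not detected and is left open: the median of 3040 lncRNA genes outside the lists was 0.05, against -0.07 for coding genes, which did not pass camera. Against whole cell, both fractions had lower lncRNA medians and passed camera, with -0.45 for pseudopodia (coding genes -0.09) and -0.53 for cell body (coding genes 0.01).

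A GA-rich motif of 7 bases in the 3' UTR was tested as a candidate explanation for the genes at least 2-fold higher in pseudopodia, with 4 tests in all. In the test planned first, the motif relative to its reversed sequence was 0.991 times as frequent in 1084 such genes as in genes matched on UTR length, level and GC content (permutation p = 0.513, 0.684 after Benjamini-Hochberg adjustment), and 606 higher genes were not searched. That control was at first set aside as unable to see the motif, and the reverse complement was tried instead, giving 1.25, over the bound of 1.1 set for it (permutation p = 5e-04, the smallest that 2000 permutations can give, adjusted 0.002). Planting 26.1% more motifs in 1124 UTRs gave 1.07 against the reversed sequence, which itself rose by 14.9%, and 1.29 against the reverse complement (permutation p = 5e-04 for each). The value of 0.991 has a spread that reaches 1.02, below the 1.07 of the planted motifs. This argues against a rise of the planted size at random positions. A smaller rise is not excluded, the controls point different ways, and the motif is otherwise left open. The value against the reverse complement may also reflect purine-rich 3' UTRs in general, which was not tested. The rules for leaving the motif and the lncRNAs open were changed after their values were seen. Under the rules set first, the value against the reversed sequence and the lncRNA median would have counted against these explanations. Permutations were reduced to 2000 after the first run, for time. Lower genes gave 1.00 and 0.959 (permutation p = 0.84 and 0.115, adjusted 0.84 and 0.23).

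The lists that differed between pseudopodia and cell body could reflect GC or length bias, or loss of scarce transcripts in libraries of low complexity. After the GC and length correction 12 of 12 lists kept direction and call, and of 1963 genes with at least 100 CPM, 642 differed 2-fold or more, 352 higher and 290 lower, which argues against both as the whole cause. Carry-over of cell body RNA in scraping, and transport within the cell, were not tested. With 3 against 3 libraries the 10 splits are too few for a share under 0.05: as many as the real 7475 genes and 12 lists came from 1 split each, the real one, and the highest others gave 0 and 10. For pseudopodia against whole cell the real 11842 genes and 15 lists stood beside 0 and 9, and for cell body against whole cell 7501 and 15 beside 0 and 12, again 1 split each. Each other split mixes the groups, which adds their difference to the spread, so its 0 genes cannot test the gene calls. In the same order of comparisons, the mixed splits still called at least 3, 4 and 9 lists. A list call at the preset correlation thus does not require the real grouping.

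Whole-cell levels lay outside both fractions for 5627 genes, 3007 above and 2620 below, FOS and NFATC2 among them. If whole cells were the sum of the fractions, few genes could do so. With library totals as the only scaling 3216 genes, or 16.6% of those tested, lay 2-fold or more outside, 2656 above and 560 below, which argues against a plain sum. After the GC and length correction 6926 lay outside, which argues against GC bias as the whole cause, with 2627 above and 4299 below. The majority turned there but not among genes 2-fold or more outside, 2220 above and 745 below with TMM and 1650 and 1162 after the correction. Time, detachment and lysis, which the labels do not give separately for whole cells, remain open and untested. For pseudopodia against both, 1 of 100 drawn splits, of 840 possible, gave as many as 5843, a share under 0.05. It was the real one, which was always included. The next, 5627, was the split that sets the 3 whole-cell libraries apart. Every other drawn split mixed libraries of different groups in its first group, and gave 0. The draws thus show that libraries differ by group, and cannot test what sets pseudopodia apart.

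Among 4 members of abundant lists with almost no counts, RPS10, RPL17 and PSMA2 had 0.723, 2.96 and 0.736 CPM in whole cell, here scaled by library total without TMM factors, against list medians of 323 and 53.7. Reads shared with an overlapping gene may explain this: median exon overlap was 35% for the 4 and 2.25% for the other members. By the bound set beforehand, 50% or more of the exons, 0 of 4 and 4 of 198 were overlapped (Fisher's exact p = 1). That bound would count against overlap, but 4 members cannot decide it, and annotated exons include rare transcripts. The rule that a lower share needs a test past 0.05 was added after this value was seen.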
